A study of Mus musculus with 2 samples.

How the data were processed

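The series holds 2 samples of RAW264.7 cells, control and Lamtor1 knockdown, with 1 array each. The labels give the same protocol for both samples, control included: infection with a lentiviral mixture of 2 vectors against Lamtor1, then limiting dilution. What the control cells received, and whether either sample is a single clone, is not given in the sources used here. Per the labels, 200 ng of total RNA per sample was reverse-transcribed from an oligo-dT primer and labelled with Cy3, so each array has 1 colour. Groups were taken from the labels alone.

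The deposited scanner files give each spot as an intensity on a linear scale. Per the submitters' processing notes, they were made with Agilent Feature Extraction 10.7.3.1. Per the file headers, the processed intensity was corrected for spatial and multiplicative trends within the array rather than for the local background of each spot, signals not above background were replaced by surrogates, and probe positions refer to the mm9 build of the mouse genome. The headers place both arrays on the same slide and in the same scan, so slide and scan do not separate the groups. The deposited value table of the series holds the same intensity rounded to 3 significant digits. The ratio of scanner to table values ran from 0.995 to 1.005 on both arrays, and the column medians were 28 for the control and 27.8 for the knockdown. Its scale is thus linear and uncentred.

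Each array carried 43020 spots that were not controls, for 39429 probes of 60 bases. On the control array 22929 spots (53.3%) were well above background by the scanner flag, and on the knockdown array 22745 (52.9%). No spot was saturated on either array. Spots marked as non-uniform or population outliers, 162 on the control and 177 on the knockdown array, were left out, which removed 9 probes. The log2 of the processed intensity was taken minus the array's 75th percentile over spots that were not controls, 1172 for the control and 1255 for the knockdown. Repeated spots of a probe were averaged in log2, and a probe counted as above background where over 50% of its spots were. For the 216 probes spotted several times and above background on both arrays, the median SD of a single-spot log2 difference was 0.0787. This covers spotting and scanning on the array, not cultures or labelling.

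Probes were named through a table of RefSeq genes of the GRCm38.p6 assembly, used for names only. Of 39429 probes, 26055 matched by accession, 3195 by symbol and 930 by a unique older symbol, and 9249 were left unnamed. A gene took the value of its brightest probe by the mean of both arrays. A gene was measured where this probe was well above background on at least 1 array and not saturated on both, which left 13772 genes. Of 298 genes at 2-fold or more with several probes above background on both arrays, 280 (94.0%) had all these probes in the same direction. For a gene above background on 1 array only, the fold is a bound, given as at least N-fold. It sets the bright value against the higher of the lowest signal well above background on the other array and the probe's own signal there. The bound holds for the processed intensity, and another background correction can give a smaller fold.

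With 1 array per group no test was possible and no p-value was computed. Genes were counted at a log2 difference of 1 or more in size. The 32 gene lists and the rules were written before the data were examined. For each list the median log2 difference over measured members was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, and given as a percentile. A list stood apart where its median lay outside the middle 95% of these. Lists with fewer than 3 measured members would have had values only, and there were none.

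The text names genes by a rule in 4 parts. The first is the Ragulator subunits and the 4 transcription factors of the TFEB family. The second is, at 2-fold or more, the 12 highest and 12 lowest genes above background on both arrays, with all other such probes in the same direction and without clone or accession names. The third is the 4 largest bounds in each direction among genes above background on 1 array. The fourth is up to 3 members of each list with the largest differences. Of the genes this rule names, 1 of the lowest is not reported here.

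The calculation was tested on simulated data made from the control array with spot noise, for the comparison of knockdown with control, with 200 genes shifted. Of the 50 genes shifted by each of 1.5, -1.5, 3 and -3 in log2, 100% passed the threshold in the right direction, and 0 of 13520 unshifted genes did. Of random lists of 30 genes drawn from 13772 genes, 6% lay outside the middle 95% with no shift and 99.5% lay above it after a shift of 0.5. The gene simulation holds spot noise only, not differences between cultures. Its noise had 1 SD for all genes, 0.0787 in log2, and the shifted genes came from those above background on both arrays. Against that noise, shifts of 1.5 or 3 could hardly fail, so it checks the calculation and not dim genes. The random lists used the measured differences of these 2 arrays, which hold no replicate cultures.

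Alternatives were normexp background correction with an offset of 50, median scaling, scaling over probes above background on both arrays, quantile normalization, cyclic loess, a stricter and no filter on dim probes, the median over a gene's probes, outlier spots kept, the value table, random lists not matched on expression, and members in no other list. The normexp setting started from the mean signal and local background of each spot rather than from the processed intensity. Leaving out the genes of chromosome 9 was added after the data were seen. Background correction and normalization used limma 3.58.1 in R 4.3.3, and the rest pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.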

Results

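Gene expression was measured in RAW264.7 cells, a mouse macrophage-like line, on 1 array of control cells and 1 array of cells in which Lamtor1 had been knocked down with short hairpin RNA from a lentivirus. Lamtor1 is the membrane anchor of Ragulator, the complex that holds the Rag GTPases on the lysosome, where they recruit the kinase complex mTORC1. The series asks how active the transcription factor TFEB, a driver of lysosome and autophagy genes that mTORC1 phosphorylates, is in cells without Ragulator. On the control array 22929 of 43020 spots (53.3%) were well above background, and on the knockdown array 22745 (52.9%). With 1 array per group, no difference given here has a replicate check, and each one describes these 2 arrays only. The number of arrays limits the precision. Levels are log2 signals relative to the 75th percentile of the same array, and differences are knockdown minus control.

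Lamtor1, the targeted gene, was 23.1-fold lower on the knockdown array, at 4.34% of the control signal. Its level was 4.10 on the control array and -0.43 on the knockdown array, a log2 difference of -4.53, and it was well above background on both. The value comes from a single probe, A_55_P2052185, which lies on chromosome 7 at 109060334 to 109060393 in the mm9 build that the files use. The files name this probe by the older symbol 2400001E08Rik. Lamtor1 ranked 68 among the genes lower in the knockdown, counted from the lowest difference. This rank runs over all 13772 measured genes. Genes above background on 1 array only entered it at their plain difference rather than their bound.

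Across all genes, 1240 of 13772 measured genes (9.0%) were at least 2-fold higher in the knockdown and 1150 (8.35%) were at least 2-fold lower. At 4-fold the counts were 581 higher and 495 lower. Among the 12565 genes well above background on both arrays, 793 were at least 2-fold higher and 693 at least 2-fold lower. With normexp background correction the counts were 789 higher and 613 lower. Without a filter on dim probes they were 1657 higher and 1760 lower. When genes above background on 1 array were counted by their bound, 1064 were at least 2-fold higher and 945 at least 2-fold lower. The median difference over all genes was -0.05.

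Among genes above background on both arrays, Cpe, the prohormone-processing carboxypeptidase E, was 529.5-fold higher in the knockdown, from a level of -4.29 to 4.76, and its 3 probes gave log2 differences of 6.30 to 10.36. Hal, the histidine-degrading ammonia-lyase, was 449.8-fold higher. Pakap was 169.8-fold higher, the serine protease gene Prss46 152-fold, and the membrane glycoprotein gene Pdpn 131-fold. Fabp4, a fatty acid carrier of macrophages and fat cells, was 95-fold higher, from -2.01 to 4.56. Tent5c was 74.2-fold higher, the efflux transporter gene Abcg2 72.2-fold, the signalling scaffold gene Card14 68.9-fold, Cd200r4 65.3-fold and the heparanase gene Hpse 63.4-fold. Ndst1, which encodes a heparan sulfate-modifying enzyme, was 65.6-fold higher by its brightest probe, but another probe of the gene gave a log2 difference of 0.59. Among genes not well above background in the control, Dio2, whose product activates thyroid hormone, was at least 1709-fold higher. Cd84 was at least 294-fold higher, the lipid phosphatase gene Plpp3 at least 239-fold, and the brightest probe named Klra8 at least 151-fold. Whether that probe tells Klra8 from related genes was not tested. These folds depend on the background correction where a gene was dim on 1 array, and the bounds hold for the scanner's processed signal only. With normexp, which shrinks such differences, Cpe was 279-fold higher, Hal 173-fold, Prss46 88.8-fold, Pdpn 33.4-fold, Card14 31.7-fold, Tent5c and Cd200r4 27.7-fold and Ndst1 20.9-fold. Dio2 was then 430-fold higher, Cd84 74.0-fold, Plpp3 70.4-fold and Klra8 38.0-fold. Every normexp fold of a gene given as a bound, these included, rests on 1 signal not well above background. Such a value is neither a bound nor a precise fold. As the median over probes, Pdpn was 54.8-fold higher, Cd84 103-fold and Ndst1 13.3-fold.

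In the other direction, Rtp4, an interferon-inducible chaperone of receptors, was 88.9-fold lower, from 3.18 to -3.30. Cx3cr1, the receptor of the chemokine fractalkine, was 81.6-fold lower, from 5.59 to -0.76, with log2 differences of -6.35 and -6.33 at its 2 probes. Fcgr1, the high-affinity receptor for immunoglobulin G, was 72.3-fold lower. The cyclophilin gene Ppic was 68.4-fold lower, the adhesion molecule gene Jaml 63.1-fold, Gypc 54.7-fold and Ranbp3l 53.9-fold. The transcription factor genes Nfix and Klf4 were 49.7-fold and 47.1-fold lower, Cyb561 42.0-fold and Scel 39.1-fold. Among genes not well above background in the knockdown, Trp53i11 was at least 198-fold lower and Serinc2 at least 104-fold. Flt1, a receptor for vascular endothelial growth factor, was at least 81.9-fold lower, and Hpgd, which degrades prostaglandins, at least 78.5-fold. With normexp these folds were smaller as well, at 53 for Rtp4, 23.1 for Fcgr1, 38.1 for Ppic, 23.2 for Jaml, 27.3 for Ranbp3l, 17.7 for Nfix and Cyb561, 20.5 for Klf4 and 16.5 for Scel. For the genes given as bounds they were 52.4 for Trp53i11, 26.3 for Serinc2, 26.6 for Flt1 and 24.3 for Hpgd. As the median over probes, Nfix was 26.6-fold and Trp53i11 116-fold lower. Of the genes named here, Prss46, Cx3cr1 and Camp lie in the distal part of chromosome 9, whose genes had a median difference of 0.37.

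**Figure D1:**
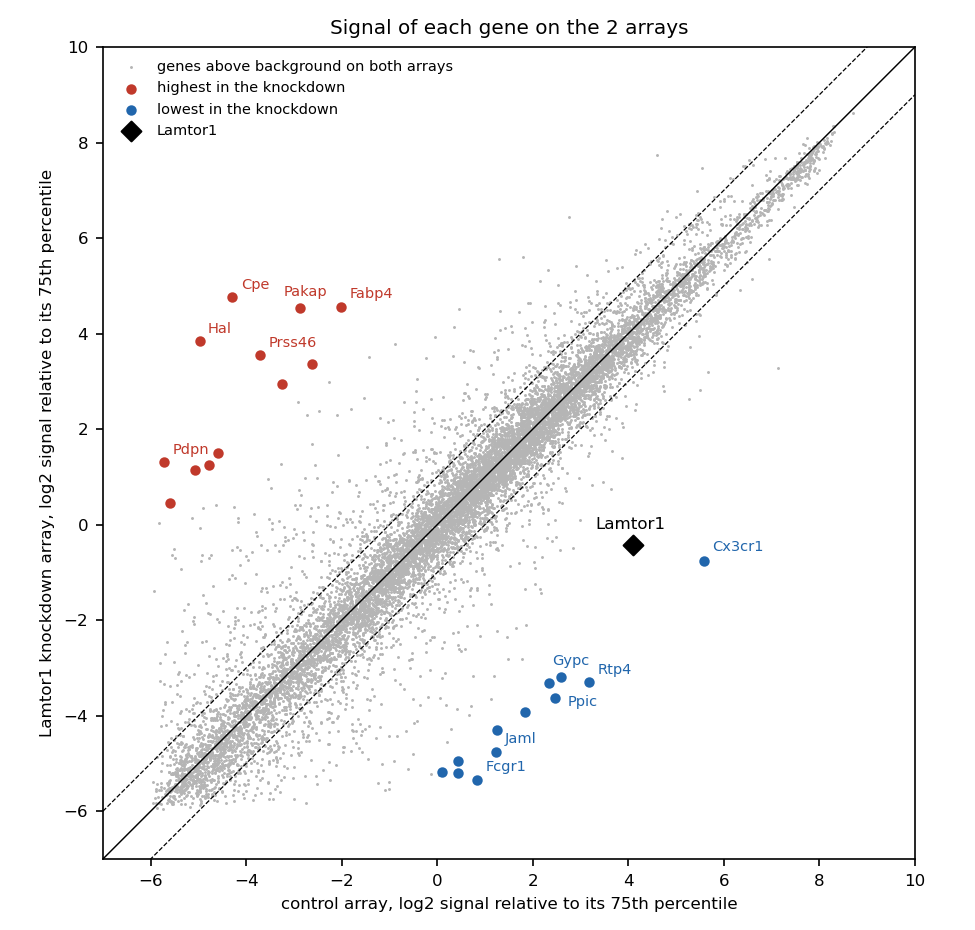
Each point is 1 gene well above background on both arrays, with its log2 signal on the control array on the x axis and on the Lamtor1 knockdown array on the y axis, both relative to the array's 75th percentile. The solid line marks equal signal and the dashed lines 2-fold; Lamtor1 lies at 4.10 and -0.43, Cpe at -4.29 and 4.76, and Cx3cr1 at 5.59 and -0.76.

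The other Ragulator subunits stayed within 2-fold. Lamtor2 had a log2 difference of -0.08, Lamtor3 of 0.80 with its 3 probes at 0.75 to 0.80, Lamtor4 of 0.56 and Lamtor5 of 0.22. In the list of Ragulator and Rag GTPases, Rragc, which encodes 1 of the Rag GTPases, was 2.34-fold higher. Rragd, another Rag GTPase gene, was not well above background in the control and was at least 1.97-fold higher (1.36-fold with normexp). Of the 10 members 2 were at least 2-fold higher, 1 of them when Rragd is counted by its bound, and Lamtor1 itself was lower. The median was 0.17, at percentile 85.5 of 10000 random lists of equal size drawn from genes of like expression, which places it inside their middle 95%. This percentile describes where a list lay on these arrays and is not a test of replicates.

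Of the transcription factors that bind the lysosomal gene motif, Tfeb was 1.62-fold lower, Mitf 1.59-fold lower and Tfe3 1.31-fold lower. Tfec was 4.30-fold higher, from -2.80 to -0.69. The median of the 4 genes was -0.53, at percentile 3.20 of the random lists, inside their middle 95%. Among mTORC1 and its upstream regulators, 3 of 24 genes were at least 2-fold higher and 1 lower, with a median of 0.06 at percentile 78.6. Fnip2 was 3.06-fold higher and its partner Flcn, the folliculin tumour suppressor, 2.22-fold higher. Ddit4, a stress-induced inhibitor of mTORC1, was 2.81-fold lower.

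Lysosome and autophagy genes were higher in the knockdown as a group. Of 131 measured members of the combined list, 105 had a difference above 0, 29 were at least 2-fold higher and 2 at least 2-fold lower. The median was 0.52, at percentile 100 of the random lists, whose middle 95% ran from -0.12 to 0.05.

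The V-ATPase, the proton pump that acidifies lysosomes, showed the highest median of all lists. All 18 measured subunit genes had a difference above 0, 11 were at least 2-fold higher and none was 2-fold lower, and the median was 1.16 at percentile 100. Atp6v0d2, a subunit gene abundant in osteoclasts, was 15.8-fold higher, from -0.05 to 3.92. Atp6v0a1 was 4.56-fold higher and Atp6v1c1 3.29-fold higher.

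Lysosomal hydrolases had a median of 0.63 at percentile 100, with 7 of 43 genes at least 2-fold higher, 1 at least 2-fold lower and 35 between. Galc, the enzyme that degrades galactosylceramide, was 3.92-fold higher and the protease gene Ctsd 3.78-fold higher, from 5.55 to 7.47. Ctsh, also a cathepsin gene, was 34.2-fold lower, from -0.12 to -5.22 (13.5-fold with normexp). Lysosomal membrane proteins had a median of 0.53 at percentile 100, with 8 of 27 genes at least 2-fold higher and none 2-fold lower. Laptm4b was 22.5-fold higher (13.5-fold with normexp), Gpr137b 6.15-fold, and the chloride transporter gene Clcn7 3.85-fold.

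Genes of the autophagy list were higher as well, mostly by less than 2-fold. Their median was 0.41, at percentile 100, but 39 of 43 genes stayed within 2-fold, 3 were at least 2-fold higher and 1 lower. The 17 genes whose symbols begin with Atg, grouped after the data were seen, had a median of 0.19 at percentile 92.9, inside the middle 95% of random lists, so they did not stand apart as the list did. Tecpr1, which acts in autophagosome maturation, was 8.16-fold higher, from 2.31 to 5.34. The receptor gene Tax1bp1 was 2.21-fold higher. Atg7, an enzyme of autophagosome formation, was 2.15-fold higher by its brightest probe, and its log2 difference was 0.92 as the median over its probes.

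The list of genes that act in feedback between mTORC1 and TFEB or are metabolic targets of TFEB had a median of 1.05 at percentile 100, with 8 of 15 genes at least 2-fold higher, 7 when counted by bounds, and 1 lower. Gpnmb, a glycoprotein of the lysosomal and melanosomal membrane, was 8.80-fold higher, from 4.59 to 7.73. Ppargc1a, a coactivator of mitochondrial genes, was not well above background in the control and was at least 2.55-fold higher (1.75-fold with normexp). Rragc, Rragd, Flcn and Fnip2 are members too, and 10 of the 15 genes are shared with other lists. The 5 remaining genes had a median of 0.13 at percentile 75.8.

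**Figure D2:**
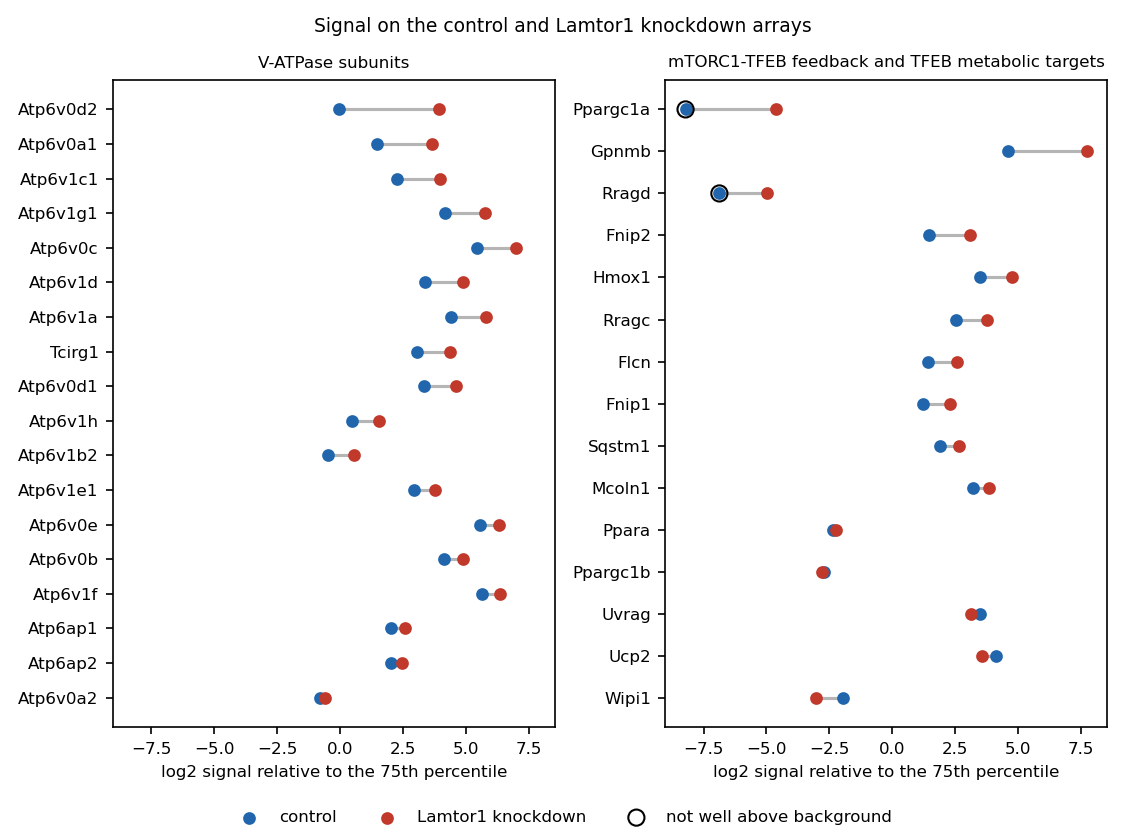
Log2 signal relative to the array's 75th percentile (x axis) of each V-ATPase subunit gene (left) and each gene of the mTORC1-TFEB feedback and TFEB metabolic target list (right), with control in blue, Lamtor1 knockdown in red and a ring where the control signal was not well above background. All 18 V-ATPase genes lie further right in the knockdown, with Atp6v0d2 going from -0.05 to 3.92; in the other list 11 of 15 do.

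The cholesterol list and the mixed list of fatty acid synthesis genes and LXR targets had medians slightly below 0. Cholesterol biosynthesis genes had a median of -0.31 at percentile 0.16, with 19 of 23 differences below 0, 1 gene at least 2-fold higher and none 2-fold lower. Tm7sf2 was 1.77-fold lower. Fdft1, the enzyme that forms squalene, was 1.84-fold lower by its brightest probe, but its log2 difference was 0.15 as the median over its probes. Srebf2, the transcription factor of the pathway, was 2.63-fold higher by its brightest probe, but its other probe was lower in the knockdown and the median log2 difference over both was 0.20. Fatty acid synthesis and LXR target genes had a median of -0.29 at percentile 1.56, with 3 of 18 genes at least 2-fold higher and 4 lower. Against random lists not matched on expression its percentile was 3.29, inside the middle 95%. The phospholipid transfer gene Pltp was 7.49-fold lower and Mylip 3.40-fold lower, while the cholesterol efflux transporter gene Abca1 was 5.78-fold higher. With normexp, Pltp was 2.92-fold lower and Abca1 3.20-fold higher.

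Genes of the ATF4 and amino acid response were lower, with a median of -0.74 at percentile 0. Of 28 members, 9 were at least 2-fold lower, 2 at least 2-fold higher and 17 between. Pycr1, an enzyme of proline synthesis, was not well above background in the knockdown and was at least 12.5-fold lower (4.45-fold with normexp). Chac1, which degrades glutathione, was 4.77-fold lower and the stress-induced gene Nupr1 4.50-fold lower.

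Cell cycle and DNA replication genes had a median of -0.33 at percentile 0.01, with 35 of 39 differences below 0 but only 2 genes at least 2-fold lower. Bub1b, a kinase of the spindle checkpoint, was 2.38-fold lower and Aurkb had a log2 difference of -0.82. Ccnd1, cyclin D1, was 2.04-fold lower, and its log2 difference was -0.93 after median scaling and -0.96 with cyclic loess or normexp. Targets of p53 had a median of 0.40 at percentile 99.9, with 5 of 19 genes at least 2-fold higher and none 2-fold lower. Phlda3 was 5.38-fold higher, the secreted factor gene Gdf15 3.67-fold (2.36-fold with normexp) and Trp53inp1 3.59-fold.

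The lists of oxidative phosphorylation, ribosomal protein and glycolysis genes lay within the random range. Oxidative phosphorylation genes had a median of -0.11 at percentile 28.6, and none of 43 reached 2-fold. Ndufa4, Ndufv1 and Ndufs8 had log2 differences of -0.58, -0.45 and 0.40. Cytosolic ribosomal protein genes had a median of -0.19 at percentile 4.47, and none of 41 reached 2-fold. Rpl35, Rpl3 and Rpl18 had log2 differences of -0.58, -0.44 and -0.42. Wider groups of translation genes, formed by the opening letters of their symbols after the data were seen, lay in part below that range. The 90 Rpl genes, which include pseudogenes, had a median of -0.21 at percentile 0.07, the 63 Rps genes, which include pseudogenes and kinases, -0.22 at 0.365, the 50 Mrpl genes -0.19 at 0.65 and the 13 Eef genes -0.30 at 1.84. The 56 Eif genes, at percentile 4.77, and the 31 Mrps genes, at 6.40, lay inside it. Glycolysis and HIF1 target genes had a median of -0.06 at percentile 57.2, with 2 of 26 genes at least 2-fold lower. Egln3, an oxygen-sensing hydroxylase, was not well above background in the knockdown and was at least 36.7-fold lower (11.8-fold with normexp). Ankrd37 and Pfkp had log2 differences of -1.32 and -0.89.

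The planned lists of NRF2 targets, endoplasmic reticulum stress and heat shock genes also lay within the random range in the main setting. The NRF2 antioxidant targets had a median of 0.08 at percentile 90.5, with 5 of 20 genes at least 2-fold higher, and the percentile was 98.9 after quantile normalization. Gsta3 was not well above background in the control and was at least 15.1-fold higher. Its fold was 9.60 with normexp and 59.7 as the median over its probes, and neither of these is a bound. Gstm1 was 3.46-fold higher and the haem-degrading enzyme gene Hmox1 2.43-fold higher. Endoplasmic reticulum stress genes had a median of 0.15 at percentile 97.1, with 1 of 21 genes at least 2-fold higher. This percentile was 98.6 after quantile and 97.9 after cyclic loess normalization. The sensor gene Ern1 was 2.04-fold higher, with log2 differences of 0.84 after normexp correction and 0.98 after scaling over probes above background, and Dnajb9 and Dnajb11 had log2 differences of 0.67 and 0.43. Heat shock protein genes had a median of 0.03 at percentile 76.6, with 1 of 12 genes at least 2-fold lower. Hspa1a was at least 2.08-fold lower (1.5-fold with normexp), Hsp90ab1 had a log2 difference of -0.53 and Dnaja1 of 0.37, though another probe of Dnaja1 gave -1.39 and the median over its probes was -0.51. The 10 Dnajb genes, a group formed by symbol after the data were seen, had a median of 0.51 at percentile 99.5, above the random range. Of other chaperone groups formed in that way, the 24 Dnajc genes (0.03, percentile 75.4) and the 9 Hspa genes (0.0064, percentile 66.0) lay inside it.

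Interferon-stimulated genes had the lowest median of all lists, -1.95, at percentile 0 of random lists whose middle 95% ran from -0.26 to 0.14. Of 32 members, 25 were at least 2-fold lower, none was 2-fold higher and 31 had a difference below 0. Besides Rtp4, the antiviral GTPase gene Mx2 was not well above background in the knockdown and was at least 22.1-fold lower (8.20-fold with normexp). Irf7, the transcription factor that amplifies interferon production, was 23.7-fold lower, from 0.29 to -4.28 (11.4-fold with normexp). With the 5 members above background on 1 array counted by their bound, 24 were at least 2-fold lower.

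Antigen presentation genes were lower too, with a median of -0.53 at percentile 0, 6 of 18 genes at least 2-fold lower and none 2-fold higher. H2-DMa, a chaperone of class II peptide loading, was 8.86-fold lower, H2-DMb1 2.91-fold and the peptide transporter gene Tap1 2.73-fold. All 3 lie close together on chromosome 17, between 34274300 and 34330913 (mm9). The window of 50 neighbouring genes that holds them had a median of -0.27, rank 260 of 264 from the highest. No median after subtracting neighbouring genes is given for this list. Inflammatory cytokines and chemokines went both ways, with 8 of 29 genes at least 2-fold higher, 9 lower and a median of 0.01 at percentile 71.2. Counted by bounds, 7 were higher and 8 lower. The 11 Ccl chemokine genes, grouped after the data were seen, had a median of 0.38 at percentile 98.3, above the random range. Il1rn, the interleukin-1 receptor antagonist, was 19.8-fold higher. Cxcl10, a chemokine induced by interferon, was 16.6-fold lower, and Ptgs2, the inducible cyclooxygenase, at least 15.5-fold lower. With normexp, Cxcl10 was 7.10-fold and Ptgs2 4.56-fold lower.

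Macrophage identity markers had a median of -0.31 at percentile 0.27, with 7 of 26 genes at least 2-fold lower and 3 higher. Besides Cx3cr1 and Fcgr1, the transcription factor gene Cebpa was 22.6-fold lower, from 0.70 to -3.80 (13.5-fold with normexp). The percentile was 3.52 when only genes above background on both arrays were used. It was 6.87 without the genes of chromosome 9, a setting chosen after the data were seen. Genes of alternative macrophage activation went both ways, with 3 of 9 at least 2-fold higher, 3 lower and a median of 0.18 at percentile 88.1. With the median over each gene's probes the percentile was 99.6. Klf4 is a member, the lectin gene Clec10a was 24.0-fold lower, and the transglutaminase gene Tgm2 was 45.0-fold higher.

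Osteoclast genes split. Of 19 members, 8 were at least 2-fold higher and 6 at least 2-fold lower, with a median of 0.30 at percentile 98.9. Counted by bounds, 7 were higher and 5 lower. Ctsk, the collagen-degrading protease of osteoclasts, was 19.1-fold higher, from 1.30 to 5.56, and Atp6v0d2 is also a member. Car2, a carbonic anhydrase, was 11.3-fold lower, from 2.15 to -1.35. Over the 16 members that belong to no other list the median was -0.31, at percentile 3.76, so the sign of the median turned. The percentile was 90.2 with the median over each gene's probes and 96.9 without chromosome 9.

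Markers of other cell types were mostly dim or near their control level. The 4 measured neutrophil markers had a median of 1.02 at percentile 98.6, with S100a8 4.22-fold higher, the elastase gene Elane 2.23-fold higher and Camp at least 1.84-fold higher. With normexp, S100a8 was 2.05-fold and Camp 1.17-fold higher. That median rests on 4 genes, and it was 0.0092 when no filter on dim probes was used. The 6 dendritic cell markers had a median of -0.21 at percentile 19.4. Among them Bst2, which is also interferon-stimulated, was 2.39-fold lower, and Zbtb46 and Irf8 had log2 differences of -0.70 and -0.27. The 5 T cell markers had a median of 0.05 at percentile 66.9. The cytokine receptor gene Il7r was 38.2-fold higher, and Lck and Cd5 had log2 differences of -0.69 and -0.63. The 5 B cell markers had a median of 0.47 at percentile 94.3, with a percentile of 98.8 when dim probes were kept. Cd22 was 2.49-fold higher, Blnk had a log2 difference of 0.96, which was 1.05 after median scaling, and Cd79b was at least 2.62-fold lower (1.46-fold with normexp). The 4 fibroblast markers had a median of 0.07 at percentile 61.7. Pdgfrb was at least 2.09-fold lower (1.96-fold with normexp), and Acta2 and Col1a2 had log2 differences of 0.12 and 0.08. The 3 epithelial markers Esrp1, Krt14 and Cldn7 had log2 differences of -0.33, -0.29 and 0.19, and their median of -0.29 lay at percentile 32.7.

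Of the 32 lists, 9 lay above the middle 95% of their random lists and 7 below it. Chance would give 1.6 of either kind if the genes of a list varied independently. Genes of a pathway need not, so the excess over 1.6 is no test. Lists also overlap, and the combined lysosome and autophagy list is counted beside its parts.

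**Figure D3:**
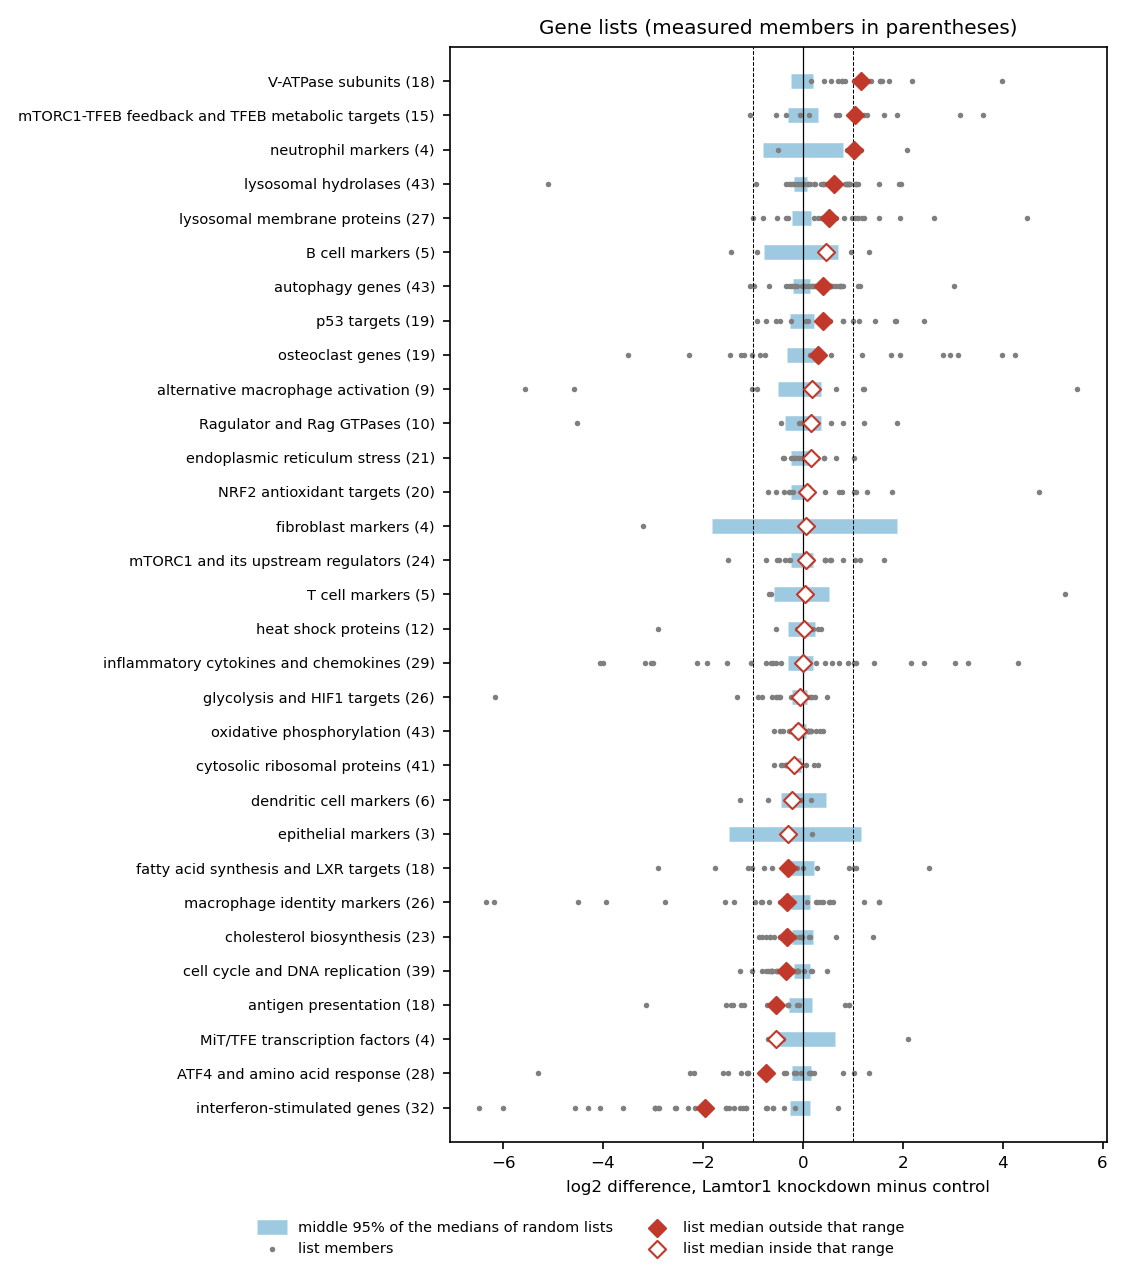
For each gene list except the combined lysosome and autophagy list (measured members in parentheses) the x axis gives log2 differences, Lamtor1 knockdown minus control, of the members (grey points) and their median (diamond), with the middle 95% of the medians of 10000 random lists as a blue bar and dashed lines at 2-fold. The V-ATPase median of 1.16 is the highest and the interferon-stimulated median of -1.95 the lowest; filled diamonds lie outside the blue bar.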

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

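Probes without a matched gene name were not part of the report's comparisons. Of 3820 such probes above background on at least 1 array, 287 were at least 2-fold higher in the knockdown than in the control and 369 at least 2-fold lower, which is 7.51% and 9.66% of them. They are listed because they hold signal in data that no comparison used. The lowest of those above background on both arrays, named LOC100048875 in the files and picked after its values were seen, had a log2 signal of 5.29 on the control and -1.05 on the knockdown array.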

How the results depend on the processing

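All alternatives were planned before the data were examined except the one without chromosome 9. Lamtor1 stayed more than 2-fold lower under each of the 10 alternatives that could give it a value. The medians of the combined lysosome and autophagy list (0.48 to 0.62) and of the hydrolase, lysosomal membrane, V-ATPase (1.06 to 1.25), autophagy, neutrophil, interferon-stimulated, ATF4, cell cycle, p53, cholesterol and antigen presentation lists kept their sign and stayed outside the middle 95% of random lists under every alternative run. The neutrophil median, over 4 genes in the main setting, ran from 0.0092 to 1.16, so its size was not stable. The genes at least 2-fold higher and lower numbered 789 and 613 with normexp, 793 and 693 among genes above background on both arrays, and 1657 and 1760 without a filter. The stricter filter tests fewer genes and no filter tests more. The normexp setting also added an offset of 50 to all probes, which shrinks the differences of dim probes most. It also started from the mean spot signal rather than the processed intensity. Input signal, correction and offset were changed together, so their parts in the lower counts cannot be told apart. Osteoclast genes had a median of -0.31 over members in no other list, the opposite sign, 0.14 with the median over probes and 0.22 without chromosome 9, each inside the range. Other medians that moved inside it were those of macrophage markers, at -0.22 with the stricter filter and -0.20 without chromosome 9, the TFEB feedback list, at 0.13 over members in no other list, and the fatty acid and LXR list, at -0.29 against unmatched random lists. Medians that moved outside it were NRF2 targets, at 0.22 with quantile normalization, endoplasmic reticulum stress, at 0.21 with quantile and 0.24 with cyclic loess normalization, B cell markers, at 0.30 without a filter, and alternative activation, at 0.53 with the median over probes. For these lists the cause was not tested. Bracketed values of named genes below are log2 differences. Among named genes, normexp brought Rragd, Ppargc1a, Ccnd1, Ern1, Hspa1a, Cd79b and Pdgfrb under 2-fold, the median over probes did so for Atg7 and Srebf2, median scaling and cyclic loess for Ccnd1 (-0.93 and -0.96) and scaling over probes above background for Ern1 (0.98). Blnk moved over 2-fold with median scaling (1.05) and cyclic loess (1.04), and none of the named genes at 2-fold or more turned its sign. Below 2-fold the sign turned for Fdft1 (0.15) and Dnaja1 (-0.51) with the median over probes, for Lamtor2 with median scaling, and for Acta2 and Col1a2 with normexp. Normexp made the folds of many named genes dim on 1 array over 1.5 times smaller. Some fell under their bound, among them Dio2, Cd84, Trp53i11 and Egln3, with log2 differences of 8.75, 6.21, -5.71 and -3.56. The median over probes made the fold over 1.5 times smaller for Pdpn, Ndst1, Nfix, Cd84 and Trp53i11. Slide as a block was not run, as both arrays share a slide, and leaving out a replicate was not run with 1 array per group. Signal over background limits the dim genes: 587 were above it only in the knockdown and 620 only in the control.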

Other observations

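The families, the genes named from them and the chromosome segment were picked after the data were seen, as were the tests of macrophage content, of osteoclast genes, of base composition and of an extra copy on chromosome 9. Genes were grouped by the letters that open their symbols. Of 205 groups of at least 8 genes, 33 lay outside the middle 95% of random lists. Chance would give 10.25 if the genes of a group varied independently. Related genes and near copies need not, so the excess over 10.25 is no test. Fatty acid binding protein genes were higher, with 5 of 8 at least 2-fold higher, 1 lower and a median log2 difference of 1.08. Besides Fabp4, Fabp3 went from -0.91 to 1.81 and Fabp5 had a log2 difference of 1.11. Fabp5 and Fabp5l2 are close copies whose probes need not tell them apart. The 14 genes of the TRAPP complexes, which tether transport vesicles, had a median of 0.41, and none of them reached 2-fold by its brightest probe. The serine protease inhibitor genes of the Serpinb group had a median of 0.62, with Serpinb1a going from -1.46 to 1.62.

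Host genes of small nucleolar RNAs, the Snhg group, were lower, with all 9 below 0, 3 at least 2-fold lower and a median of -0.79. Snhg1, Snhg6 and Snhg7 had log2 differences of -1.23, -1.22 and -1.12. The 32 histone genes of the cluster on chromosome 13 had a median of -0.65, with 8 at least 2-fold lower and 1 higher. Histone genes are near copies of each other, so a probe can read several of them, and most of their transcripts lack the tail that an oligo-dT primer needs. The Klf transcription factor genes had a median of -0.58 over 12 genes, 3 of them at least 2-fold lower, with Klf4 lowest and Klf11 at -1.63. Sulfotransferase genes of the Chst group went far in both directions, with Chst1 at -4.34 and Chst11 at 4.93. The Chst median ranged from -1.09 to -0.27 over the settings tried, and the medians of the other groups named here kept their sign under each of them.

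Lysosome and autophagy genes were higher in the knockdown, and an offset between the arrays that changes with signal strength was argued against, as the lower of the medians under quantile and cyclic loess normalization was 0.53. Base composition of the probes was argued against, as its trend ran only from -0.08 to 0.02 over 10 bins, and random lists matched on it and on expression had 0.058 as the upper end of their middle 95%. Gains or losses of chromosome segments were argued against, as the median was 0.52, at percentile 100, after subtracting the 50 nearest genes, which moved members by -0.48 to 0.28. A difference between the cells of the 2 samples unrelated to Lamtor1, such as clonal origin, cannot be told apart from the knockdown, as there was 1 knockdown array and whether either sample is a single clone is not given. An effect of the Lamtor1 knockdown on these genes, which the design names, may therefore be one source but stays untested.

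Interferon-stimulated genes were lower in the knockdown, on 12 chromosomes, with a median of -1.95, while random lists matched on base composition and expression had -0.27 as the lower end of their middle 95%, which argues against base composition as the whole source. Segments gained or lost are argued against too, as the median was -1.87 after subtracting the 50 nearest genes, which moved members by -0.16 to 0.15. Fewer macrophages in the knockdown culture would lower all abundant macrophage markers alike, but the 21 markers brighter than the median gene of the control had a median of -0.45, with 9 of them above 0 and 6 at least 2-fold lower, so they were not lower alike. Interferon present in the control culture, rather than a loss in the knockdown, cannot be told apart, because there was 1 control array, and an effect of the Lamtor1 knockdown stays open as untested. Of 15 interferon genes with a probe, 6 were well above background in the control and 5 in the knockdown, and 0 of the 6 could be placed at least 2-fold lower in the knockdown. The 6 were dim on the control array, with levels from -5.96 for Ifna11 to -3.76 for Ifnl3. For the dimmest, Ifna11, a 2-fold fall would have gone under background. Its signal of -7.72 on the knockdown array was not well above background, so the count of 0 leaves this gene undecided.

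Genes on chromosome 9 were higher together in the knockdown, with a median of 0.19 over its 726 genes against -0.12 to -0.0039 for the other chromosomes, of which chromosomes 7, 15 and 17 lay below and chromosome 11 above random sets, and 7 of the 8 highest of 264 windows of 50 neighbouring genes lay on it. A split placed where the contrast was largest set apart 236 distal genes between 96586830 and 124023007 (mm9), with a median of 0.37, or 1.34-fold over the median of the other chromosomes, while the 490 proximal genes had a median of 0.11, also above random sets. Because that split was chosen on the same values, chromosome and split were chosen again from every other gene, and of the 119 left-out genes of the distal part 81.5% lay above the median of all genes, with medians of 0.34, 0.47 and 0.23 for dim, middle and bright genes. This is consistent with an extra copy of the segment in the knockdown cells, or a copy missing in the control, as a hypothesis that needs DNA and leaves the smaller proximal shift open. Base composition of the probes and genes of the lists lying in the segment were argued against as the whole source, as random sets matched on composition and expression had 0.033 as the upper end of their middle 95% and the median was 0.37 without the list genes.

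A further hypothesis was that the osteoclast list reflects an osteoclast programme beyond the lysosomal genes it shares. The 16 osteoclast genes in no other list had a median of -0.31 at percentile 3.76, inside the middle 95% of random lists. Their quartiles lay at -1.19 and 2.03, so a median over genes that went far in both directions leaves the hypothesis open.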
